A study of Gallus gallus with 8 samples.

How the data were processed

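Nrf2 CUT&Tag peak lists from broiler (Gallus gallus) liver were analysed for 8 samples, 4 in the PT group and 4 in the HT group, with 1 list per sample. Groups and replicate numbers came from the sample titles. The submitters' processing notes name cutadapt 1.9.2, Bowtie2 2.2.4 and the galGal6 build, with no settings. The deposited peak names begin with MACS, a peak caller; its version, its settings, the treatment of duplicate reads and any control library are not given in the sources used here. Each deposited list has 5 columns and no header: chromosome, start, end, peak name and the score the authors' caller gave the peak. The scale of the score is not stated. Scores ran from 40 to 3100, so each list holds only peaks at or above a minimum. Each sample has its own list and the lists differ. Whether each was called on the reads of that sample alone is not stated. Read counts are not in the lists, so no interval for counting error was possible and the depth of each sample is unknown.

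Starts were raised by 1 base to give 1-based positions. Per list, the number of peaks, the covered length, the median peak width and the percent of peaks on Z, W and the mitochondrial chromosome were computed. The percent of peaks on chromosomes 1 to 5, 6 to 10, 11 to 33 and on scaffolds (220 scaffolds had a peak) was added after the data were seen. Pairs of lists were compared by the Jaccard index of covered bases and by the percent of peaks overlapping by at least 1 bp. Peaks of all lists that overlapped or touched were merged into 30246 regions, and a list held a region when at least 1 bp of a peak lay in it. For identical ends, only regions in which both lists of a pair had a single peak were compared, and both start and end had to match to the base. The overlap of merged PT and HT regions was set against 200 circular shifts of the PT regions along each chromosome with a fixed seed. Scores were used only to rank or filter peaks within a list. The comparison of identical ends, the shifts and the division of Z at 70 Mb and into parts of 10 Mb were also chosen after the data were seen.

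Group means were compared by an exact two-sided permutation test over 70 relabellings, and the overlap difference over the 35 splits of the lists into 4 and 4, one-sided. The smallest p either can give is 0.0286. Benjamini-Hochberg adjustment was over 10 tests, of which the 4 on numbered chromosomes and scaffolds were added after the data were seen. Counts of one-group regions were set against the same 35 splits. Apart from what is described as added or chosen after the data were seen, the tests, the alternatives and the rule for named regions were fixed before the data were examined. The rule took the 15 regions per direction found in all 4 lists of one group and none of the other, and the 10 found in all 8 lists, with the highest mean percentile of the score within each list. Regions on unplaced scaffolds count among these but are given only by number. The code was tested on simulated lists for PT against HT, with regions set too far apart to merge. Over 43769 simulated regions, all 4000 HT-only, 2000 PT-only and 700 common regions were recovered. That layout fixed the outcome for correct code, so it checks the counting only. Closely spaced peaks and fragments shared between lists were not simulated. In draws of 8 random numbers, not lists, with no group difference, 1.8% passed the threshold of 0.05, where the design allows 2.86%.

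Alternatives were the highest-scoring 50% of each list, the same number of peaks per list (5120), chromosomes only, no Z and W, merging over 500 bp, a cover of 50% of the region, the replicate number as a block, and leaving out each list in turn. Alternatives added after the data were seen were regions in which no 2 lists share peak ends, Z below 70 Mb, regions off scaffolds and outer chromosome ends, and lists without peaks under 260 bp. The gene table at hand is of assembly GRCg7b, which differs from galGal6, and no genome sequence was used here. The 5 planned results that need either were therefore not run: peaks at promoters, genes with peaks in one group (both directions), 18 gene lists fixed beforehand, and the antioxidant response element. The genes the rule lists by name are not reported for the same reason. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.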

Results

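Binding of Nrf2 was profiled in broiler liver by CUT&Tag, in which an antibody directs a transposase to cut and tag the DNA beside the bound protein. Nrf2 is the transcription factor that switches on antioxidant and detoxification genes, and the series title names heat-stressed chickens and Nrf2-regulated genes as its subject. The 8 samples fell into 2 groups of 4, called PT and HT after their titles. The HT labels give high temperature as the treatment. The PT labels are in conflict: one field names treatment with phloretin, a polyphenol of apples, another calls the same samples normal, and the protocol field gives high temperature for all 8. The comparison is therefore given as HT against PT, with no statement on what PT birds received. One list of peaks per sample was analysed, with 66669 peaks in all. The lists hold no read counts, so the sequencing depth of each sample is unknown. No label says that the samples of a group came from separate birds. The p-values therefore compare only these lists, whose spread may be technical. They also assume independent lists, which the identical peak ends within groups described below put in doubt.

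The HT lists were longer than the PT lists. They held 10281 ± 789 peaks (SD, n = 4 lists) against 6386 ± 916 in PT (SD, n = 4 lists), a ratio of 1.61. The shortest HT list had 9437 peaks and the longest PT list 7302. Peaks covered 6.12 ± 0.368 Mb per HT list and 3.62 ± 0.470 Mb per PT list. Both differences gave p = 0.0286 in an exact two-sided permutation test, the smallest p that 70 relabellings of 4 against 4 lists can give (Benjamini-Hochberg adjusted p = 0.0357 over 10 tests). With the 5120 highest-scoring peaks of each list the difference in covered length was 0.406 Mb, against 2.50 Mb over the full lists. The median peak was 497.5 ± 4.43 bp wide in HT and 483.25 ± 5.32 bp in PT, with the same exact permutation p = 0.0286. That difference of 14.25 bp changed sign, to -4.25 bp (exact permutation p = 0.743), when each list was held to its 5120 highest-scoring peaks. Leaving out any 1 HT list took its p to 0.0571 in the exact permutation test, and without chromosomes Z and W it was 7.75 bp (exact permutation p = 0.0857).

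The PT and HT lists marked largely different parts of the genome. The Jaccard index, the number of bases covered by both lists over the number covered by either, averaged 0.468 within PT (0.367 to 0.596, 6 pairs) and 0.490 within HT (0.442 to 0.609, 6 pairs). Between the groups it averaged 0.110 (0.102 to 0.119, 16 pairs). Within-group overlap exceeded between-group overlap by 0.369, more than in any other of the 35 splits of the 8 lists into 4 and 4 (exact one-sided permutation p = 0.0286, adjusted p = 0.0357). On average 18.9% of the peaks of a PT list overlapped a given HT list (16.6% to 23.0%), and 11.4% of the peaks of an HT list overlapped a given PT list (10.3% to 12.6%). The overlap still exceeded that of randomly placed regions. Of the 12274 merged PT regions on chromosomes, 1753 (14.3%) overlapped a merged HT region, against a mean of 254.6 (209 to 315) over 200 random circular shifts, a ratio of 6.89.

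Lists of the same group shared many peaks with the same first and last base. Among regions in which both lists of a pair had a single peak, 60.0% to 83.1% of the PT pairs' peaks and 55.0% to 70.8% of the HT pairs' peaks had identical ends. Between the groups the share was 0.0893% to 0.549%, or 1 to 6 peaks per pair. In the regions that all 8 lists held, peak ends were identical for 60.0% of the peaks compared within PT, 32.0% within HT and 0.307% between the groups.

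**Figure D1:**
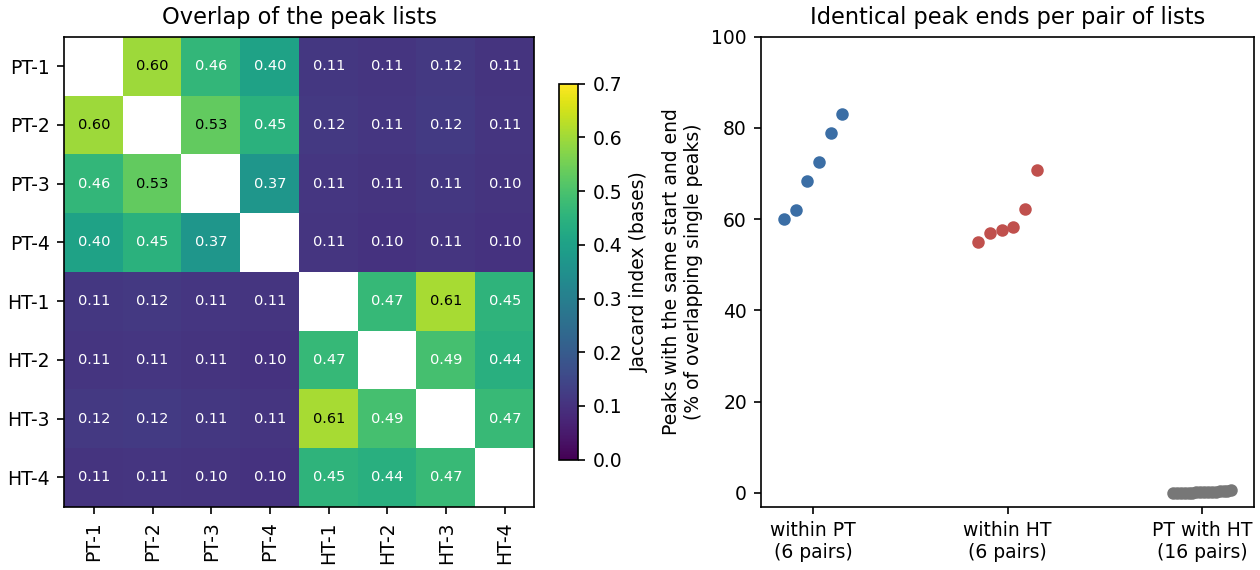
Left, Jaccard index of covered bases for each pair of the 8 peak lists, from 0.367 to 0.609 within the groups and from 0.102 to 0.119 between them. Right, percent of overlapping single peaks with identical start and end, 1 point per pair of lists: 55.0% to 83.1% within the groups (6 pairs each) and at most 0.549% between them (16 pairs).

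Merging the peaks of all lists gave 30246 regions, and most were found in few lists. A single list accounted for 16922 of them (55.9%). All 4 HT lists and no PT list held 4234 regions, while all 4 PT lists and no HT list held 2066. All 8 lists held 728 regions, or 430 with the strongest 50% of each list and 436 when peaks had to cover 50% of the region. The highest count of such one-group regions in any other split of the lists was 11. The excess of HT regions went with list length: with 5120 peaks from every list there were 1707 HT-only and 1620 PT-only regions. At least 2 lists gave identical peak ends in 95.9% of the HT-only and 98.9% of the PT-only regions, and 175 and 23 regions remained without such a pair. All 4 lists gave the same ends in 50.2% of the HT-only and 62.6% of the PT-only regions.

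**Figure D2:**
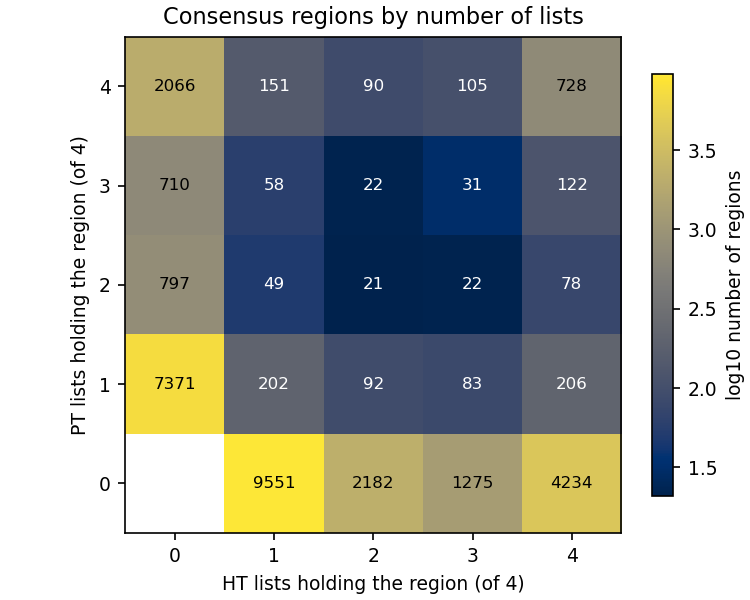
Number of merged regions by how many of the 4 HT lists (horizontal) and 4 PT lists (vertical) held them, coloured by log10 of the number. The counts are high along both edges, with 4234 regions in 4 HT and 0 PT lists and 2066 in 4 PT and 0 HT lists, and at the corner of 728 regions found in all 8.

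Chromosomes 1 to 5 held 42.3% of the 4234 HT-only regions and 51.5% of the 2066 PT-only regions, and scaffolds 7.27% and 9.05%. The regions named here were picked by score and are not a sample of these sets. Of the 15 HT-only regions with the highest mean score percentile within their lists, 4 were on unplaced scaffolds, 3 on chromosome Z, 4 on chromosomes 11 to 33, 2 on chromosomes 6 to 10 and 2 on chromosomes 1 to 5. The first of these on a chromosome was 2:14507538-14508015 (galGal6), 478 bp wide, with peak scores of 282.34 to 370.05 as the authors' caller gave them. It was followed by 25:1984966-1986868 (scores 223.88 to 259.76), Z:28502976-28503211 (152.46 to 245.03), 24:32904-33439 (187.84 to 198.42) and Z:75802289-75803886 (182.64 to 209.78). Further down were 1:1014773-1015244, 6:517671-518928 and Z:74188174-74189352. All 15 were 236 to 1903 bp wide, and in 2 of them all 4 HT lists gave the same peak ends.

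Of the 15 PT-only regions picked in the same way, 12 were on chromosomes 1 to 5, with 1 each on Z, W and chromosome 28 and 0 on scaffolds. First was Z:59603880-59604151, 272 bp wide, with scores of 412.44 to 423.59 in the 4 PT lists. Next were 1:172115526-172115785 (scores 379.28 to 397.91), 3:71394257-71394528 (343.78 to 358.17), 3:103146834-103147143 (305.52 to 344.59) and 2:73882573-73884035 (322.67 to 335.82). The W region was W:5737217-5737876 (249.31 to 256.8). These 15 regions were 204 to 1463 bp wide, and in 12 of them all 4 PT lists gave the same peak ends. Some scores were also equal between lists. PT lists 1, 2 and 4 gave 423.59 in the first region, and PT lists 1, 2 and 3 gave 397.91 in the second. A score could also recur in different regions, as 224.05 did in 3:45117081-45117284 and 28:3463259-3463467. An equal score alone therefore does not show that lists share fragments. Many of the 15 regions were narrow. The first 4 were 272, 260, 272 and 310 bp wide, against a median PT peak of 483.25 bp, while the next was 1463 bp wide. The treatment of duplicate reads is unknown, so these regions cannot be read as the strongest binding sites. Genes at the named regions are not given, because no annotation of galGal6 was used here.

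The regions found in all 8 lists had a median width of 1173.5 bp, against 499 bp over all regions. Part of this gap is built in, since these regions merge peaks of 8 lists and a wide region is more readily met by every list. Scaffolds held 21.6% of them, against 5.22% of all regions. Of those on chromosomes, 29.4% lay within 1 Mb of the start of a chromosome or of its last peak, against 10.3% of all regions on chromosomes. The highest-scoring peak of each of the 8 lists fell in 27:293479-297884, with scores of 2799.81 to 2828.63 in PT and 3100 in every HT list. Whether 3100 is a ceiling of the score is not known. That region was followed on the chromosomes by 22:143731-144790, 3:105175515-105181159, 31:2945470-2947874, 10:20861796-20862938, 15:267940-271577, 7:19668-24406 and 25:491412-493094. With the treatment of duplicate reads unknown, these regions too cannot be read as the strongest binding sites. Without scaffolds and the outer 1 Mb of each chromosome, 403 of the 728 regions were left.

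The groups also differed in how peaks were spread over the chromosomes. The smaller chromosomes, 11 to 33, took 26.1 ± 0.606% of the peaks of an HT list and 21.8 ± 0.430% of those of a PT list (SD, n = 4 lists each). Chromosomes 1 to 5 took 43.2 ± 1.15% in HT and 48.8 ± 2.13% in PT. Each difference gave an exact permutation p of 0.0286 (adjusted p = 0.0357), and for chromosomes 1 to 5 it rose to 0.0571 in the exact permutation test without HT list 1, 2 or 3. Shares on chromosomes 6 to 10 were 11.3 ± 0.194% and 11.7 ± 0.559% (exact permutation p = 0.343), and those on scaffolds 7.99 ± 0.611% and 9.41 ± 1.44% (exact permutation p = 0.114). Both calls depended on the setting. The difference on chromosomes 6 to 10 was -0.854 points with the same number of peaks per list and -0.576 points on chromosomes only, each with an exact permutation p of 0.0286, but 0.0443 points, not past the threshold, without Z and W. That on scaffolds was -1.85 points without PT list 4 (exact permutation p = 0.0286), but turned to 0.514 points in the strongest 50% of each list (exact permutation p = 0.457) and 1.16 points with the same number of peaks per list (exact permutation p = 0.229). These shares of numbered chromosomes and scaffolds were chosen after the data were seen. All 32 numbered chromosomes with peaks had more peaks per list in HT, by 1.32 to 1.52 times on chromosomes 1 to 5 and by 1.51 to 3.40 times on chromosomes 11 to 33. Chromosome 21 had the highest ratio, with 72.25 ± 6.85 peaks against 21.25 ± 5.12.

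The sex chromosomes moved in opposite directions. In birds, males carry a pair of Z chromosomes and females 1 Z and 1 W. Z held 10.9 ± 0.223% of the peaks of an HT list and 7.12 ± 0.901% of those of a PT list. W held 0.444 ± 0.0465% in HT and 1.23 ± 0.202% in PT. Both differences gave an exact permutation p of 0.0286 (adjusted p = 0.0357). In peaks per list, Z had 1125 ± 79.1 in HT against 452.25 ± 72.6 in PT, a ratio of 2.49. W had 45.5 ± 3.79 in HT against 77.5 ± 1.73 in PT, a ratio of 0.587 and the only chromosome with fewer peaks in HT. The ratio on Z was 3.35 below 70 Mb (561.5 ± 71.5 against 167.5 ± 52.8 peaks) and 1.98 from 70 Mb on (563.25 ± 8.88 against 284.75 ± 22.6). Z held 483 HT-only and 120 PT-only regions, and W held 9 HT-only and 36 PT-only regions. No list had a peak on the mitochondrial chromosome.

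**Figure D3:**
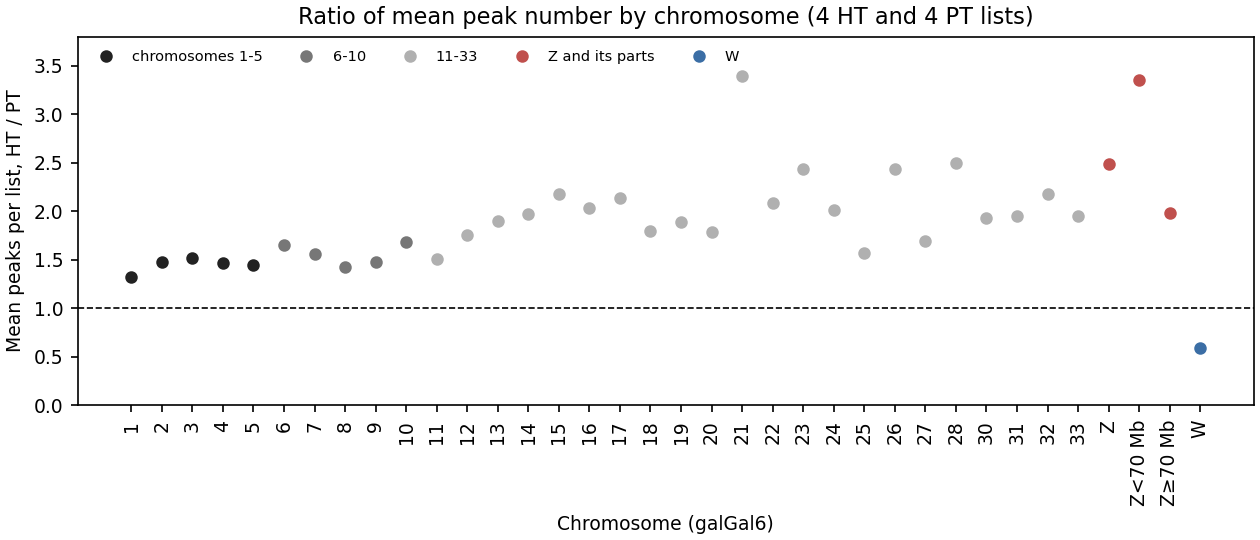
Mean number of peaks per list in HT divided by that in PT (4 lists each) for each galGal6 chromosome, with Z also split at 70 Mb; the dashed line marks equal numbers. The numbered chromosomes lie between 1.32 and 3.40, Z is at 2.49 and W at 0.587.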

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

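Of 124 alternative values of the planned results, 105 kept their direction and their side of the threshold, or stayed within 1.5 times for counts of regions. The difference in covered length was 0.406 Mb with equal list lengths and 1.44 Mb in the strongest 50%, against 2.50 Mb. That in median width was 23.25 bp in the strongest 50%. Of 51 values for the shares of numbered chromosomes and scaffolds, 40 did so. Neither count shows stability. Most of each comes from leaving out 1 list, a weak check where lists share peak ends, and the replicate block changes no value. Exceptions follow, their causes untested unless the setting gives them. Regions sharing no peak ends, Z below 70 Mb, regions off scaffolds and chromosome ends, lists without peaks under 260 bp and these shares were chosen after seeing the data. The HT minus PT difference in median width ranged from 12.4 to 16.8 bp when each list was left out (p up to 0.0571 in the exact permutation test; 3 lists against 4 can give 0.0286). It was 7.75 bp without Z and W and -4.25 bp with the same number of peaks per list. That setting gave 1707 HT-only regions. The strongest 50% of each list, which has fewer peaks, gave 1921 HT-only, 985 PT-only and 430 common regions. A 50% cover gave 436 common regions, leaving out scaffolds and outer 1 Mb ends 403, and asking for no shared peak ends 175 HT-only and 23 PT-only regions. The share on scaffolds turned to 0.514 points higher in HT in the strongest 50% and to 1.16 points higher with equal list lengths, without passing the threshold. That without PT list 4 was -1.85 points (exact permutation p = 0.0286). The share on chromosomes 6 to 10 turned to 0.0443 points without Z and W, and passed the threshold at -0.854 points with equal list lengths and -0.576 points on chromosomes only. That on chromosomes 1 to 5 ranged from -6.48 to -4.83 points when each list was left out, with p up to 0.0571 in the exact permutation test. With the replicate block the differences were 3894.75 peaks, 2.50 Mb, 14.25 bp and, for shares on Z, W, chromosomes 1 to 5 and 11 to 33, 3.83, -0.791, -5.61 and 4.34 points. Their p of 0.125 is the smallest that an exact sign-flip permutation test of 4 pairs can give, so the block says nothing on stability. No sign was seen that the numbers pair the lists: correlations of deviations were -0.00128, 0.00735, 0.0102 and -0.00319, and 1 of 4 PT lists correlated best with its own number. Only 2060 of the 30246 regions were found in both groups, so this check may miss a pairing. Not run were promoter, gene, gene list and motif results with their alternatives. Read depth, which limits how many peaks a list can hold, is unknown.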

Other observations

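Regions differed by chromosome in how often the other group shared them. On Z and W part of this is built in, since a group with more peaks there meets more regions of the other. HT lists held 2.49 times the PT peaks on Z and 0.587 times on W. Of the 618 Z regions held by all 4 HT lists, 135 (21.8%) were also in a PT list, and of the 237 held by all 4 PT lists, 117 (49.4%) were in an HT list. On W, 17 of 26 regions of all 4 HT lists (65.4%) were in a PT list, while 25 of 61 regions of all 4 PT lists (41.0%) were in an HT list. Scaffold regions of all 4 HT lists were in a PT list for 227 of 535 (42.4%), against 343 of 2134 (16.1%) on chromosomes 1 to 5. PT list 4 differed most from the other PT lists in several values. Its share of peaks on Z was 5.80%, against 7.40% to 7.83%, and its median width 491 bp, against 479 to 482 bp. Its Jaccard index with the other PT lists was 0.367 to 0.446, against 0.464 to 0.596 among these. Without it there were 2641 PT-only regions, against at most 2132 without any other list. By Dixon's test, which was run on 9 measures per list within each group and has little power with 4 values, 0 lists passed the critical value.

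The comparisons over splits of the lists were set before their results were seen. The test on 10 Mb parts of Z was set before its own result, but after the higher Z level had been seen. The other tests below were chosen after. The 4234 HT-only regions exceeded the highest count of 11 in the other splits, with 1 of 35 splits, the real one, as large. For the 2066 PT-only regions it was likewise 1 of 35 splits, with 11 as the highest other. The overlap difference of 0.369 was reached by 1 of 35 splits, with 0.0854 as the highest other. In each case 1 of 35 is the smallest share that the splits can give. It speaks against chance assignment of the lists to groups only as far as the lists are independent. Lists of a group that share DNA fragments would give the same outcome whatever the treatment.

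The lists of a group cannot be taken as independent, so their SDs may not measure the spread between birds or libraries. The p-values assume independent lists, so they cannot be read as evidence of a difference between birds. In regions that all 8 lists held, identical peak ends made up 32.0% of the peaks compared within HT (at least 29.4% per pair of lists), more within PT, and 0.307% between the groups (at most 0.619% per pair), which argues against sharp binding sites or the peak caller fixing the ends. No single nonzero start offset took over 0.996% of the peaks compared between groups, which argues against a shift from processing. A candidate explanation is that the lists of a group hold partly the same DNA fragments, through repeated sequencing, pooling or exchange of reads; these were not told apart. Whether shared fragments also account for the one-group regions cannot be told apart from other causes: at least 2 lists shared peak ends in 95.9% or more of these regions, but also in 74.6% (HT) and 92.4% (PT) of the regions in all 8 lists, and a treatment effect stays open as untested.

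The opposite movement of Z and W may reflect birds of different sex in the groups, with more ZZ material in HT and more ZW in PT. W was not absent from HT, however. Each HT list held 40 to 48 W peaks, and 9 W regions were in all 4 HT lists and no PT list. A difference in Z copies would cover the whole chromosome, and all 7 parts of 10 Mb of Z below 70 Mb had ratios of 2.81 to 4.39, above the highest of the 58 such parts of chromosomes 1 to 5 (1.02 to 1.83), although the higher Z level itself prompted the hypothesis and chromosome 21 reached 3.40. Longer HT lists alone are argued against by the W ratio of 0.587, since every numbered chromosome was above 1. Repeats of the distal Z are argued against because Z below 70 Mb stood at 2.28 times the median ratio of chromosomes 1 to 5. An HT excess on small chromosomes is argued against by chromosomes 3, 4 and 5, whose last peaks end nearest to that of Z. They reached at most 1.52. Over all 32 numbered chromosomes the median ratio was higher, at 1.85, and 1 of them, chromosome 21, stood above Z below 70 Mb. Treatment stays open and untested, base composition was not examined, and the labels used here give no sex.

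The larger number of HT-only than PT-only regions, a ratio of 2.05, may come in large part from the longer HT lists, since the ratio was 1.05 with the same number of peaks per list. Among the few regions in which no 2 lists shared peak ends, 175 against 23, the ratio was 7.61 over the full lists. Whether the lists are longer through deeper sequencing, higher signal or more binding stays open, because the lists hold no read counts.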
